A study of Mus musculus with 17 samples.

How the data were processed

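RNA was sequenced from CD8 T cells of the mouse spleen that carried the congenic marker Thy1.1, per the labels. There were 17 libraries in 4 groups that the labels name by the targeted gene: 5 Rosa KO libraries, used here as the control, and 4 libraries each of Asxl1 KO, Dnmt3a KO and Tet2 KO. The labels' protocols name a column kit for RNA isolation (Direct-zol) and a stranded total RNA library kit (TruSeq). The molecule field of the labels reads genomic DNA, while the series type and these protocols describe RNA, and the files were read as RNA-seq. The number after each group name (Asxl1 KO 3) is the replicate number of the labels. Nothing in the labels says that replicates came from separate animals or cultures, so each p-value measures only the spread between these libraries, which may be technical.

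The authors deposited 1 table per library with raw counts per gene, next to an NCBI gene identifier and a symbol, for 24594 genes in the same order. The submitters' processing notes name STAR 2.5.3a, DESeq2 1.26.0 and the mouse build mm10, without their roles. The counting tool, the annotation and whether counting used the strand are not given in the sources used here. Reads of genes that overlap or lie antisense to each other, and of near-identical paralogs, could therefore have been split or shared, and such genes are named as uncertain. Of the 24594 identifiers, 24570 matched the RefSeq annotation of GRCm38.p6, the assembly of which mm10 is another name, and coordinates are 1-based in that build. No gene of the mitochondrial genome was listed, and no table held a total or an unassigned category. Total counts ran from 6625833 (Rosa KO 5) to 40701203 (Rosa KO 4), with a median of 21642477. The ribosomal RNA gene Rn45s took 1.21 to 4.40% of the counts and the 20 most abundant genes 7.66 to 12.4%. Over the 28 pairs of libraries from the same group, a chi-square of the counts per degree of freedom lay between 20.6 and 272, so no pair agreed within sampling noise and none was counted as 1 sample.

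The library numbers in the labels fell into 3 separated runs. Run 1 (numbers 63 to 68) held Rosa KO 1, Dnmt3a KO 1 and 2 and Asxl1 KO 1. Run 2 (81 to 86) held Dnmt3a KO 3 and 4, Tet2 KO 1 and 2 and Asxl1 KO 2. Run 3 (124 to 136) held Rosa KO 2 to 5, Tet2 KO 3 and 4 and Asxl1 KO 3 and 4. The labels do not call these runs batches. No Rosa KO library lay in run 2 and no Dnmt3a KO library in run 3, so Dnmt3a KO shared a run with only 1 Rosa KO library. Run alone accounted for a median of 25.6% of a gene's variance in log2 CPM (12.5% by its degrees of freedom), and group alone for 19.0% (18.8%).

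Counts were scaled by TMM and tested with edgeR 4.0.16 in R 4.3.3, by a quasi-likelihood F test (robust) with group and run as terms, over all 17 libraries (11 residual degrees of freedom). The filter filterByExpr (minimum count 10, total 15) left 13881 genes. The common biological coefficient of variation was 0.604. P-values were adjusted by the Benjamini-Hochberg method over the tested genes of a comparison, and a gene passed at an adjusted p under 0.05. Counts-per-million (CPM) are TMM-scaled, and log2 CPM has a prior count of 2. All 6 comparisons between the 4 groups were made.

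The groups, the model, 25 gene lists and the rule for named genes were fixed before the data were examined. For each knockout against Rosa KO, the rule names the 3 targeted genes, 12 T cell genes whether or not they passed, and up to 4 passing members of each list. It adds up to 8 rises and 8 falls of the largest size among passing genes with a mean of at least 5 CPM in the higher group and the same sign without the run term. Predicted genes, pseudogenes, small RNAs, antigen receptor segments and members of the lists for other cell types were left out of that last part. For each pair of knockouts it names the 5 highest and 5 lowest genes. Some results for genes that the rule names are not reported here. Any gene named outside the rule is said to have been chosen after its values were seen.

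The lists covered stem-like and progenitor T cell genes, terminal exhaustion, effector and cytotoxic genes, tissue residency, interferon response, proliferation, glycolysis, oxidative phosphorylation, the cytosolic ribosome, p53 response, Polycomb and its deubiquitinase, DNA methylation machinery, Hox genes, immediate early genes and histone genes. Markers of B cells, plasma cells, myeloid cells, neutrophils, dendritic cells, erythroid cells and platelets, CD4 and regulatory T cells, NK cells and gamma delta T cells, and sex-linked genes, made up the rest. Of the 25 lists, 23 had at least 5 tested members. These were tested with camera in limma 3.58.1 (preset correlation 0.01, p-values adjusted over the lists of a comparison), and again with a correlation estimated for each list and with fry, which tests whether a list's genes move one way on balance. Some genes stand in more than 1 list.

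The edgeR step was tested on simulated counts for the 13881 genes with 200 changed genes. It recovered 17% of 2-fold and 56% of 4-fold changes with the Asxl1 KO and Rosa KO libraries. For Dnmt3a KO the shares were 16% and 55%, for Tet2 KO 13% and 45%. Of its calls, 1 of 74, 6 of 77 and 2 of 60 were false. None of 20 unchanged random lists passed, which does not test lists of correlated genes.

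Alternatives fixed in advance were size factors from DESeq2 (RLE), a CPM filter and no filter, DESeq2 1.42.0 as the test, no run term, the replicate number as a block with and without the run term, the libraries of 2 groups or of 1 run alone, each library left out in turn, and lists without shared genes. Further alternatives were chosen after seeing the data. They left out Asxl1 KO 1 and Tet2 KO 2, or Asxl1 KO 3 and 4, took the mean log2 CPM of the B cell, myeloid and CD4 lists as covariates, or removed a trend with transcript length and GC content in each library. For overlaps between comparisons that share the Rosa KO libraries, 20 simulations of unchanged groups and 10 splits of the controls were made. Other splits of the libraries into groups of the same sizes were fitted with libraries exchanged across runs and, as chosen after seeing the data, only within runs.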

Results

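Gene expression was measured by RNA-seq in CD8 T cells from mouse spleen after targeting of 1 of 3 regulators of chromatin or DNA methylation that are recurrently mutated in clonal hematopoiesis. Asxl1 is a subunit of the Polycomb deubiquitinase complex, Dnmt3a is a de novo DNA methyltransferase, and Tet2 oxidises 5-methylcytosine. The series title asks how such regulators act on the stemness of CD8 T cells during immunotherapy. Each knockout had 4 libraries, and 5 libraries labelled Rosa KO served as the control. Total counts were 19384141, 12831920, 27092024, 40701203 and 6625833 in Rosa KO 1 to 5 and 18591728, 17387403, 22056899 and 18014394 in Asxl1 KO 1 to 4. They were 27248878, 21642477, 22733933 and 27133683 in Dnmt3a KO 1 to 4 and 30084945, 23124533, 13890261 and 16389059 in Tet2 KO 1 to 4. Between 12901 and 17940 genes had at least 1 count.

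The targeted genes were examined first, in every library. Asxl1 (NCBI gene 228790, mm10 chromosome 2, 153345830 to 153404007) had 70.3, 146, 87.3 and 114 CPM in Asxl1 KO 1 to 4, against 103 ± 32.8 CPM in Rosa KO (SD, n = 5). Dnmt3a (gene 13435, chromosome 12, 3801559 to 3914443) had 88.1, 71.7, 115 and 76.3 CPM in Dnmt3a KO 1 to 4, against 64.8 ± 27 CPM in Rosa KO (n = 5). Tet2 (gene 214133, chromosome 3, 133463677 to 133545136) had 216, 254, 129 and 125.1 CPM in Tet2 KO 1 to 4, against 161 ± 20.1 CPM in Rosa KO (n = 5). None of the targeted genes passed the edgeR test in its own knockout, with log2 fold changes of −0.13 ± 0.21 for Asxl1 (SE, adjusted p = 0.836), −0.06 ± 0.28 for Dnmt3a (0.978) and −0.26 ± 0.23 for Tet2 (0.735). A gene edited by a small insertion or deletion can keep its RNA level, so the counts do not check the labels, and the groups are taken as labelled. The antisense gene Dnmt3aos overlaps Dnmt3a, and the counts may not separate them.

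Asxl1 KO was compared with Rosa KO to ask which genes differed when Asxl1 was targeted. Effector and cytotoxic genes were lower as a list (adjusted p = 3.29e-14, adjusted p = 0.0662 with an estimated correlation), and the receptor genes Tnfrsf9, Lag3 and Pdcd1 rose. Zeb2 (gene 24136, chromosome 2, 44983512 to 45117442), a transcription factor of terminal effector differentiation, fell from 1081 ± 218 CPM in Rosa KO to 261 ± 58.4 CPM in Asxl1 KO (SD, n = 5 and 4). That was a log2 fold change of −2.27 ± 0.21 (SE, adjusted p = 4.5e-07). Gzma (gene 14938, chromosome 13, 113093824 to 113100981), which encodes a granzyme, fell by 1.81 ± 0.17 on the log2 scale (4.5e-07). S1pr5 (gene 94226, chromosome 9, 21242917 to 21248443), a receptor for tissue egress, fell by 2.04 ± 0.23 (1.18e-05). The costimulatory receptor gene Tnfrsf9 rose from 21.7 ± 12.8 to 115 ± 48.2 CPM, a log2 fold change of 2.63 ± 0.30 (1.18e-05). Tcf7 (gene 21414, chromosome 11, 52246527 to 52283383), the transcription factor of stem-like T cells, rose by 1.94 ± 0.26 (8.63e-05), with 157 ± 151 CPM in Asxl1 KO and 36.1 ± 37 CPM in Rosa KO. In both groups the run 1 library held the highest Tcf7 level, 383 CPM in Asxl1 KO 1 and 102 CPM in Rosa KO 1. Within run 3 alone (2 Asxl1 KO against 4 Rosa KO libraries) the log2 fold changes were −2.46 for Zeb2, −1.75 for Gzma, −1.95 for S1pr5, 2.72 for Tnfrsf9 and 2.09 for Tcf7. Within run 1 (1 library each) they were −1.31, −1.80, −1.57, 2.07 and 1.90.

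Among the genes named in advance, the inhibitory receptor genes Pdcd1 (log2 fold change 0.97 ± 0.18, adjusted p = 0.00429) and Lag3 (1.27 ± 0.20, 0.000593) and the exhaustion factor Tox (0.56 ± 0.14, 0.0349) rose in Asxl1 KO. The short-lived effector marker Klrg1 (−1.69 ± 0.28, 0.0011), Cx3cr1 (−0.98 ± 0.24, 0.0376) and the granzyme gene Gzmb (−0.61 ± 0.13, 0.0145) fell. Slamf6, a surface marker of progenitor cells, was at 0.86 ± 0.24 (0.0614) and did not pass. Neither did Il7r at 0.93 ± 0.38 (0.242), Havcr2 at 0.20 (0.669) or Ifng at −0.33 (0.607). Within run 3 Slamf6 was at 0.38 (0.364), Il7r at 0.80 (0.342), Havcr2 at 0.40 (0.299) and Ifng at −0.57 (0.0241), which passed. Within run 1 (1 library each) they were at 2.02, 1.77, −0.40 and 1.01, with Havcr2 and Ifng turned in direction. Further rises of large size were seen in Ier3 (2.49 ± 0.45, 0.00335) and in Muc4, Igsf9b, Mettl27, Ret, Ifngas1 and Prelid2. These last 6 had log2 fold changes from 2.31 to 6.60 and adjusted p from 0.0193 to 0.0484. The largest falls included Cdc20b (−6.28 ± 0.81, 6.55e-05), Retsat (−2.77 ± 0.43, 0.000677), the potassium channel gene Kcnj8 (−2.39 ± 0.42, 0.00299) and the chemokine gene Ccl9 (−2.37 ± 0.28, 2.31e-05). Zfp839 (−2.45, 0.0337), Ccdc146 (−3.78, 0.0441) and Gpx8 (−4.13, 0.0383) were also among them. Cdc20b spans Gzma and Gpx8, Tcf7 overlaps the end of Skp1, Ccdc146 overlaps Fgl2 and Muc4 overlaps Muc20. Reads of these may not be separated. In all, 113 of 13881 genes were higher and 114 lower by the edgeR test. Of the 45 called genes that the rule named, 37 moved the same way in 4 of 4 Asxl1 KO libraries against the Rosa KO mean. Within run 3 36 of the 45 passed and 45 kept their sign. Within run 1, in a fit with 1 residual degree of freedom, 16 passed and 44 kept their sign, with Klf6 at 0.0075. There 14 were over 1.5 times smaller, such as Pdcd1 (0.36), Klrg1 (−0.81), Cx3cr1 (−0.45), Cd7 (0.80) and Il18rap (−0.81). Leaving out 1 library gave 80 genes, 29 higher and 51 lower, in place of 227 (without Asxl1 KO 3), 123 (Asxl1 KO 4), 55 higher and 71 lower genes (Rosa KO 5) or 373 (Asxl1 KO 2). Of the 45 named genes 21 kept their call without each of the 9 libraries in turn. The model with no run term gave 23 genes (7 higher and 16 lower), and covariates for other cell types 27 (9 and 18). Zeb2, Gzma, S1pr5, Ccl9, Cdc20b and Tnfrsf9 passed in both of these settings. Tcf7 (adjusted p = 0.188 and 0.0996), Pdcd1 (0.188 and 0.203), Lag3 (0.249 and 0.164) and Tox (0.368 and 0.446) passed in neither.

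**Figure D1:**
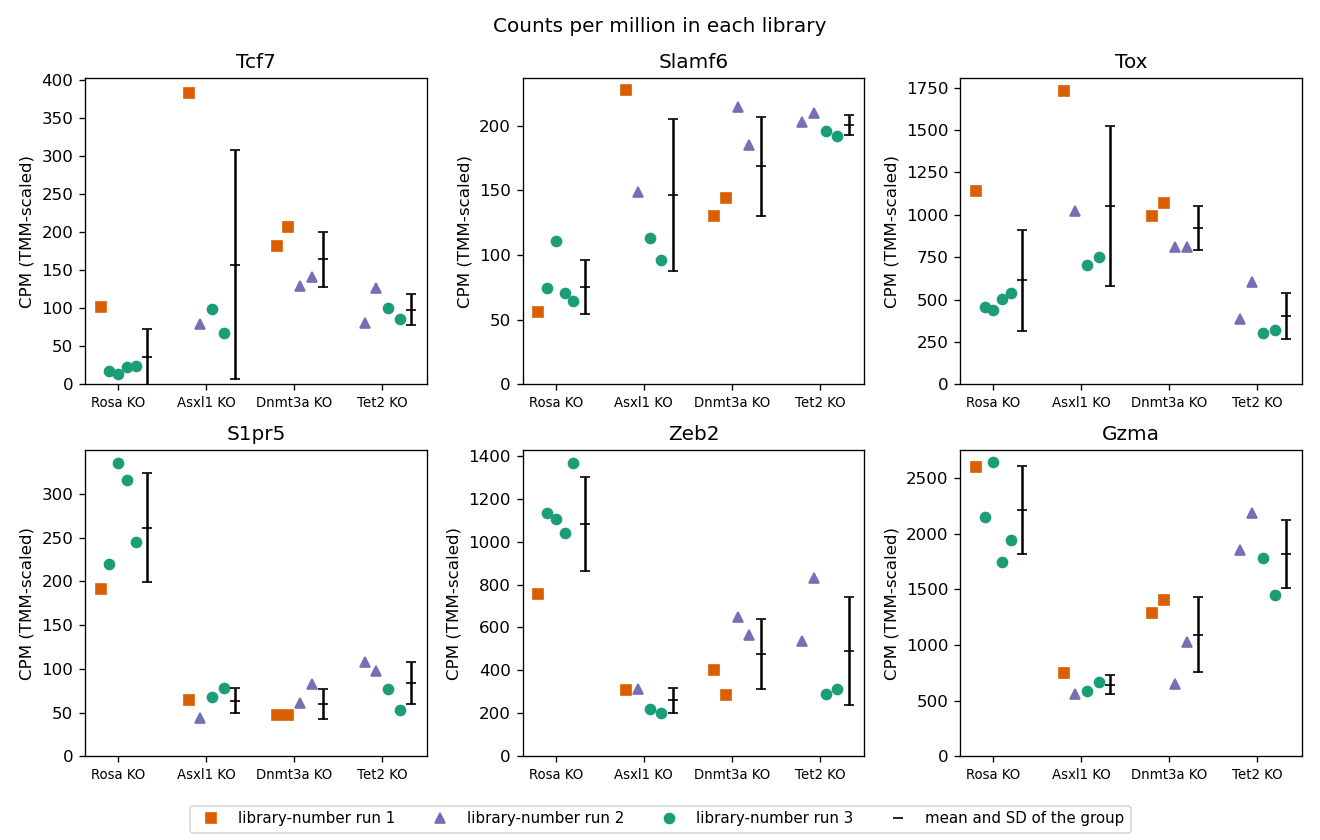
Level of 6 genes in each of the 17 libraries, in TMM-scaled CPM on linear axes from 0, by group (run by colour and shape, bars mean and SD). S1pr5 and Zeb2 were lower in the 3 knockouts than in Rosa KO, whose Zeb2 mean was 1081 CPM, and Gzma in Asxl1 KO and Dnmt3a KO but not past the test in Tet2 KO (−0.20, adjusted p = 0.739), and Rosa KO 1 held the highest Tcf7 value of its group at 102 CPM.

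Of the 33 effector and cytotoxic genes, 13 fell and 1 rose in Asxl1 KO (16 and 7 when adjusted over the list alone), with a median log2 fold change of −0.38. Beyond Zeb2, Gzma and S1pr5, the cytokine receptor subunit Il18rap (−1.45 ± 0.19, adjusted p = 8.14e-05) and the integrin Itgam (−1.32 ± 0.18, 0.000104) fell. So did Klrb1c (−2.62 ± 0.38, 0.000677), which belongs to a family of near-identical NK receptor genes. The list was lower by camera (adjusted p = 3.29e-14, adjusted p = 0.0662 with an estimated correlation). Among 27 terminal exhaustion genes, 5 rose and 1 fell (10 and 1 adjusted over the list alone), led by Cd7 (1.71 ± 0.21, 3.26e-05), Lag3 and the serpin Serpina3g (1.13 ± 0.18, 0.000823). The repressor Bhlhe40 fell (−1.15 ± 0.16, 0.000219). That list had a median of 0.30 and was higher (0.000133, adjusted p = 0.0662 with an estimated correlation), a call lost without both Asxl1 KO 3 and 4 (0.108). Of 26 stem-like and progenitor genes, 4 rose, namely Tcf7, the T-box factor Eomes (1.15 ± 0.19, 0.00128), the chemokine gene Xcl1 (2.27 ± 0.39, 0.00199) and Nsg2 (1.67 ± 0.41, 0.0385). The 1 that fell was Lef1 (−1.11 ± 0.29, 0.0484), a partner of Tcf7 in Wnt signalling named after its value was seen, which did not pass with no run term (0.505) or with covariates for other cell types (0.419). Adjusted over the list alone, 7 rose and 3 fell. The median was 0.33 and the list was higher (0.00574, adjusted p = 0.248 with an estimated correlation). Without Rosa KO 1 (adjusted p = 0.27) or without Asxl1 KO 1 (0.28) the stem-like list did not pass, nor did it with genes shared between lists left out (0.117) or by fry (0.0662).

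Respiratory chain, ribosomal and proliferation genes lay higher in Asxl1 KO as lists (adjusted p = 0.175, 0.340 and 0.340 with an estimated correlation), with few single members past the test. Of 40 oxidative phosphorylation genes 3 rose (17 adjusted over the list alone), including the cytochrome c oxidase subunits Cox5a (0.85 ± 0.17, adjusted p = 0.0106) and Cox5b (1.06 ± 0.23, 0.0178) and Ndufa4 (0.94 ± 0.24, 0.0484). That list passed at 1.83e-12 (adjusted p = 0.175 with an estimated correlation). Of 46 ribosomal protein genes 2 rose, Rpl12 (0.64 ± 0.15, 0.0256) and Rps28 (0.83 ± 0.20, 0.0303), and 18 when adjusted over the list alone. This list passed at 5.26e-10 (adjusted p = 0.340 with an estimated correlation). None of 40 proliferation genes passed alone and 6 rose when adjusted over the list alone. Their median was 0.60, with an adjusted p of 4.74e-07 (adjusted p = 0.340 with an estimated correlation). Of 34 interferon response genes, Ifi27l2a (0.79 ± 0.18, 0.0178) and Bst2 (0.95 ± 0.23, 0.0303) rose, 4 adjusted over the list alone. As a list they passed at 0.024 (adjusted p = 0.221 with an estimated correlation). The interferon call was lost without Rosa KO 4 (0.068) or Asxl1 KO 4 (0.105), with genes shared between lists left out (0.0634) and with covariates for other cell types (0.306). Among 22 immediate early genes, Klf6 fell (−1.29 ± 0.26, 0.0112) and Ier3 rose, 8 and 2 when adjusted over the list alone. As a list they were lower at 3.37e-06 (adjusted p = 0.215 with an estimated correlation). Among 12 tissue residency genes Itga1 (−1.19 ± 0.27, 0.0201) and Cd69 (−0.91 ± 0.23, 0.0441) fell and Xcl1 rose, 4 and 2 when adjusted over the list alone. Residency genes did not pass as a list (0.609). The ribosomal (0.761) and interferon (0.147) lists did not pass with no run term, nor without both Asxl1 KO 3 and 4 (0.284 and 0.108).

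Markers of other cells moved with Asxl1 KO as well. The 18 B cell genes averaged 5.87 and 5.78 log2 CPM in Asxl1 KO 3 and 4, against 7.67 to 7.86 in the 4 Rosa KO libraries of the same run, and 6.25 in Asxl1 KO 1 against 5.50 in Rosa KO 1. None of them passed alone, over all genes or adjusted over the list alone. The B cell list was lower (median −0.81, adjusted p = 0.000658, adjusted p = 0.533 with an estimated correlation). It did not pass without Asxl1 KO 3 (0.15) or Asxl1 KO 4 (0.23), and turned in direction without both (0.0014). With covariates, of which the B cell list is one, neither it (0.936) nor the plasma cell list (0.906) passed. The 8 plasma cell genes were lower at 0.0365 (adjusted p = 0.447 with an estimated correlation), with 0 passing alone. This call was lost without Rosa KO 2 (0.065), Rosa KO 3 (0.078), Rosa KO 4 (0.069), Asxl1 KO 3 (0.20) or Asxl1 KO 4 (0.26). Of 12 NK cell markers, which include Gzma, Klrb1c and Eomes, 3 fell, among them Il12rb2 (−2.03 ± 0.39, 0.00502), and 1 rose (3 and 2 adjusted over the list alone). The NK cell list was lower at 0.00027 (adjusted p = 0.0662 with an estimated correlation). Il12rb2 overlaps Serbp1, which is expressed at a far higher level. Of 12 pan T cell genes, chosen after the data were seen, Lat (1.33, 8.63e-05), Cd3g (0.83, 0.00432), Cd3d (0.79, 0.0087), Cd2 (0.64, 0.0383) and Zap70 (0.85, 0.0424) rose. Lat alone of these 5 passed with no run term (0.00859) and with covariates for other cell types (0.0124). Asxl1 KO 3 and 4 also had the most genes with at least 1 count, 16862 and 17940.

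Dnmt3a KO against Rosa KO asked the same of the DNA methyltransferase. Effector and cytotoxic genes were lower as a list (adjusted p = 1.12e-35, adjusted p = 0.00695 with an estimated correlation), and so were NK cell genes (0.000117, adjusted p = 0.0187 with an estimated correlation). Klrb1c fell from 221 CPM in Rosa KO to 16.6 CPM (log2 fold change −3.65 ± 0.46, SE, n = 4 and 5, adjusted p = 0.000421) and S1pr5 from 261 ± 62.1 to 60 ± 16.7 CPM (−2.14 ± 0.27, 0.00038). Kcnj8 fell from 88.4 ± 26.1 to 6.99 ± 2.82 CPM (−3.44 ± 0.51, 0.0013). Zeb2 (−1.69 ± 0.23, 0.000421), Itgam (−1.36 ± 0.21, 0.00131) and Gzma (−1.19 ± 0.19, 0.0019) fell as well. Tcf7 rose by 1.79 ± 0.31 (0.0051), with 164 ± 35.9 CPM in Dnmt3a KO against 36.1 ± 37 CPM in Rosa KO. Ttn, the gene of the muscle protein titin, rose by 2.04 ± 0.36 (0.00881), from 29.8 ± 17.8 to 239 ± 149 CPM. Within run 1, the only run with both groups (2 Dnmt3a KO libraries and Rosa KO 1), the log2 fold changes were −1.99 for Klrb1c, −1.999 for S1pr5, −2.82 for Kcnj8, −1.14 for Zeb2 and 0.93 for Tcf7. Of these only S1pr5 passed there, in a fit with 1 residual degree of freedom, from the 2 Dnmt3a KO libraries, so that the lone libraries were assumed to vary like them. Of the 21 called genes that the rule named 5 passed within run 1 and 21 kept their sign. Over 1.5 times smaller there were Klrg1 (−0.72), Cxcl10 (0.82), Itga1 (−1.01), Ccl9 (−1.56), Klrb1c and Tcf7.

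In total 5 genes were higher and 25 lower in Dnmt3a KO among 13881 tested by edgeR. With only the libraries of the 2 groups 22 were higher and 21 lower, 13 of these 43 in common with the 30. The numbers were 27 and 10 within run 1, and 118 and 191 by DESeq2. Of the 21 called genes that the rule named, 20 moved alike in 4 of 4 Dnmt3a KO libraries, against mostly run 3 controls. The other rises were in the chemokine gene Cxcl10 (2.02 ± 0.40, adjusted p = 0.0203), in Kbtbd11 (1.38, 0.0452) and in the nucleotide enzyme Dut (1.23, 0.0257). Further falls were seen in the lipid receptor Gpr55 (−2.35 ± 0.41, 0.00582), Ccl9 (−2.35 ± 0.32, 0.000421), Cmklr1 (−1.83, 0.04999), and 2 more NK receptor genes, Klra9 (−2.54 ± 0.36, 0.000456) and Klrc2 (−1.97 ± 0.30, 0.00152). Klrg1 (−1.78 ± 0.33, 0.00881) and Gzmb (−0.87 ± 0.15, 0.00685) fell. Pdcd1 (0.16, 0.91, at −0.30 within run 1), Lag3 (0.51, 0.576), Tox (−0.01, 0.992) and Havcr2 (−0.29, 0.792) did not pass. Nor did Slamf6 (0.96 ± 0.28, 0.233), Il7r (0.55, 0.826), Cx3cr1 (−0.94, 0.271) or Ifng (−0.59, 0.684). Klra9, Klrc2 and Klrb1c belong to families of close paralogs, and Cxcl10 overlaps Art3. Without 1 library in turn the count lay between 21 and 36. Of the 21 named genes 14 kept their call in each fit, and Gzmb lost it without Rosa KO 1 (adjusted p = 0.056). In the model with no run term 19 genes passed, 15 of them in common, without Tcf7 (0.183) or Zeb2 (0.15). With covariates for other cell types 3 genes passed, Klrb1c, Ttn and Kbtbd11.

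Of the 33 effector and cytotoxic genes, 14 fell and 0 rose in Dnmt3a KO (19 and 1 adjusted over the list alone). The median was −0.91. Among 27 terminal exhaustion genes 2 fell, the G protein regulator Rgs1 (−1.55 ± 0.20, 0.000421) and the ectonucleotidase Entpd1 (−0.90 ± 0.18, 0.021). None rose, and adjusted over the list alone 6 fell and 1 rose. The median was −0.14 and the list passed as lower at 0.0143 (adjusted p = 0.221 with an estimated correlation). It did not pass without Rosa KO 1 (0.51) or Dnmt3a KO 1 (0.083). Tcf7 was the 1 stem-like gene of 26 to rise (5 adjusted over the list alone). The stem-like list had a median of 0.43 and was higher at 0.000117 (adjusted p = 0.165 with an estimated correlation). That call was lost without Rosa KO 1 (0.32) or with covariates for other cell types (0.0579). Proliferation genes (median 0.67, 3.24e-11, adjusted p = 0.222 with an estimated correlation) and ribosomal genes (0.34, 1.61e-11, adjusted p = 0.326 with an estimated correlation) were higher as lists. So were glycolysis genes (0.24, 0.00105, adjusted p = 0.221 with an estimated correlation) and oxidative phosphorylation genes (0.23, 0.00022, adjusted p = 0.470 with an estimated correlation). No member of these 4 lists passed over all genes, and 1, 0, 3 and 0 passed when adjusted over the list alone. With no run term the ribosomal and oxidative phosphorylation lists passed in the opposite direction (9.13e-05 and 0.0133) and the glycolysis list did not pass (0.279). Covariates for other cell types also ended the glycolysis call (0.0932). The oxidative phosphorylation call was lost without Rosa KO 1 (0.13) or Dnmt3a KO 4 (0.070). Itga1 was the 1 tissue residency gene to fall (−1.62 ± 0.31, 0.0124), and 2 fell and 2 rose adjusted over the list alone. That list did not pass (0.131), but was lower with genes shared between lists left out (0.0338).

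Other cell types also differed in Dnmt3a KO. The 11 CD4 and regulatory T cell markers were higher (median 0.96, adjusted p = 0.00105, adjusted p = 0.0383 with an estimated correlation), with 0 passing over all genes. Adjusted over the list alone 3 rose, among them Cd4 (2.93 ± 0.96, adjusted p = 0.40 over all genes), named after its value was seen. With covariates for other cell types, which include CD4 markers, this list did not pass (0.881). The NK cell list was lower (median −0.66, 0.000117, adjusted p = 0.0187 with an estimated correlation), with 2 members falling, Klrb1c and Gzma, and 3 adjusted over the list alone. The B cell list was higher (0.30, 0.0255, adjusted p = 0.786 with an estimated correlation), with 0 passing members either way. That B cell call was lost without Rosa KO 1 (0.28, with the direction turned), Dnmt3a KO 1 (0.093), Dnmt3a KO 2 (0.087) or Dnmt3a KO 3 (0.29).

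Tet2 KO was compared with Rosa KO for the methylcytosine oxidase. Lists of stem-like, ribosomal and proliferation genes were higher, and those of effector and exhaustion genes were lower. Of these the exhaustion list kept its call with an estimated correlation (adjusted p = 0.0352). The others did not, with adjusted p = 0.0742 for stem-like and ribosomal genes, 0.0814 for proliferation and 0.0938 for effector genes with an estimated correlation. Tcf7 rose by 1.95 ± 0.27 on the log2 scale (SE, n = 4 and 5, adjusted p = 0.000268), with 98.1 ± 20.5 CPM in Tet2 KO against 36.1 ± 37 CPM in Rosa KO. Slamf6 rose from 75.3 ± 20.9 to 200 ± 7.79 CPM (1.28 ± 0.23, 0.00411). Il7r, the receptor chain for the survival cytokine IL-7, rose by 2.23 ± 0.40 (0.0108). The largest rise was in the ephrin receptor gene Epha3, from 1.19 ± 0.66 to 24.6 ± 19.8 CPM (4.25 ± 0.65, 0.000584). The chemokine receptor gene Ccr2 rose from 285 to 848 CPM (1.11 ± 0.16, 0.00044). Entpd1 fell from 172 ± 84.3 to 60.9 ± 7.16 CPM (−1.40 ± 0.16, 5.9e-05), Zeb2 by 1.67 ± 0.22 (0.00011) and S1pr5 by 1.80 ± 0.25 (0.000347). Within run 3 (2 Tet2 KO and 4 Rosa KO libraries) the log2 fold changes were 2.24 for Tcf7, 1.28 for Slamf6, 3.46 for Epha3, 0.95 for Ccr2, −1.29 for Entpd1, −1.95 for Zeb2 and −2.11 for S1pr5. Each of these passed there, while run 1 held no Tet2 KO and run 2 no Rosa KO library.

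Of the 13881 genes, 137 were higher and 67 lower in Tet2 KO. There were 7 higher and 16 lower with no run term, 12 and 21 without Tet2 KO 3, 23 and 24 without Tet2 KO 4, and 333 and 308 by DESeq2. Further rises were in the protease inhibitor gene Ctla2a (1.88 ± 0.23, adjusted p = 7.87e-05), Xcl1 (2.22 ± 0.42, 0.00538), Klrb1f (2.00, 0.0214), Spock2 (2.81, 0.0439) and Eva1b (1.93, 0.0414). Further falls were in Gpr55 (−3.13 ± 0.39, 9.15e-05), the incretin receptor gene Glp1r (−2.95 ± 0.45, 0.00113), Cd200r2 (−5.78 ± 1.10, 0.00588), the adhesion receptor gene Adgrg1 (−1.90 ± 0.32, 0.00201), Lim2 (−2.90, 0.0444) and Sept4 (−1.78, 0.0387). Tox (−0.65 ± 0.15, 0.0249) and Klrg1 (−1.27 ± 0.30, 0.0305) fell. Pdcd1 (−0.12, 0.887), Lag3 (−0.29, 0.639), Havcr2 (−0.11, 0.9), Gzmb (−0.27, 0.437), Cx3cr1 (−0.68, 0.285) and Ifng (−0.77, 0.234) did not pass. Within run 3 Cx3cr1 (−1.12, 0.00369) and Ifng (−1.04, 0.000406) passed as lower. Klrb1f and Cd200r2 have close paralogs, and Slamf6 overlaps a predicted gene. Of the 48 called genes that the rule named, 31 moved alike in 4 of 4 Tet2 KO libraries. Within run 3 43 of them passed, 48 kept their sign, and Spock2, Klrb1f, Eva1b, Lim2 and Sept4 did not pass. Among the other 17 were ribosomal, respiratory and cell division genes such as Rps20, Cox5a and Ccnb2, each higher than the Rosa KO mean in 2 of 4. Without 1 library the count was 33 (Tet2 KO 3), 47 (Tet2 KO 4), 86 (Rosa KO 5), 91 (Rosa KO 4) or 122 (Tet2 KO 1) in place of 204. Of the 48 genes 16 kept their call throughout. Slamf6 lost it without Tet2 KO 3 (adjusted p = 0.065), Il7r without Tet2 KO 3 (0.065) or Tet2 KO 4 (0.064) and Xcl1 without Tet2 KO 4 (0.059). When no run term was used 23 genes passed, Entpd1, Epha3, Gpr55, S1pr5, Ccr2 and Adgrg1 among them and Tcf7 (0.723) and Zeb2 (0.186) not.

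**Figure D2:**
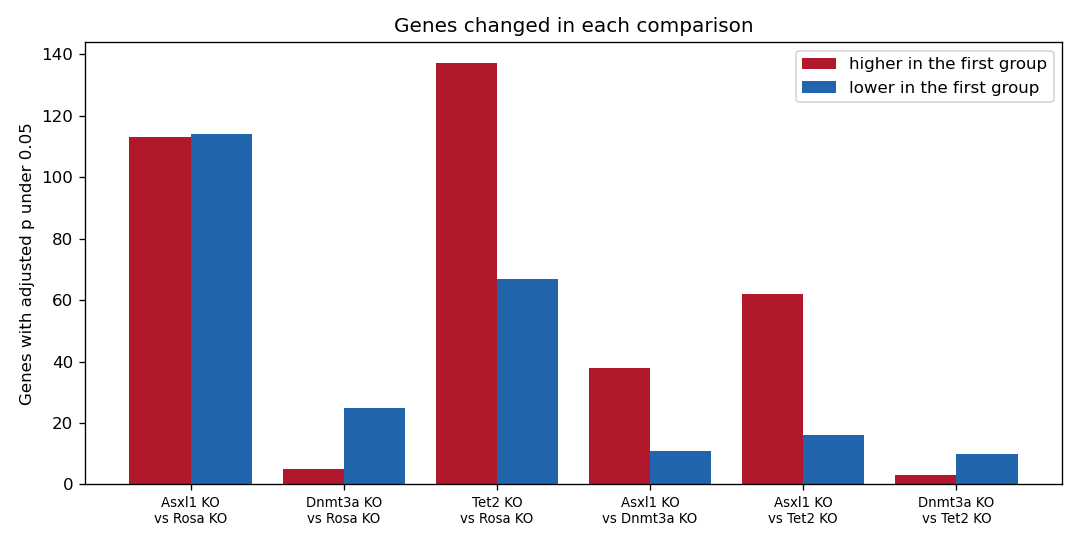
Number of genes that passed the edgeR test (adjusted p under 0.05, 13881 genes tested) in each of the 6 comparisons, as bars from 0 for genes higher and lower in the first-named group. Asxl1 KO against Rosa KO gave 113 and 114 genes, and Dnmt3a KO against Tet2 KO gave 3 and 10.

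Of the 46 ribosomal protein genes, 19 rose and 0 fell in Tet2 KO (41 rose adjusted over the list alone), such as Rps20 (0.75 ± 0.14, adjusted p = 0.00434), Rplp0 (0.90 ± 0.17, 0.00593) and Rpl35 (0.90 ± 0.18, 0.00864). Their median was 0.59 and the list passed at 1.87e-38 (adjusted p = 0.0742 with an estimated correlation). Of 40 oxidative phosphorylation genes 4 rose (27 adjusted over the list alone), namely Uqcrh (0.66 ± 0.15, 0.0244), Cox5a (0.77 ± 0.18, 0.0298), Atp5d (0.78, 0.0435) and Cox5b (0.95, 0.0456). The list passed at 7.43e-18 (adjusted p = 0.0742 with an estimated correlation). Of 40 proliferation genes 7 rose (22 adjusted over the list alone), including the cyclins Ccnb2 (1.43 ± 0.28, 0.00851) and Ccna2 (1.29 ± 0.29, 0.027) and the replicative helicase subunits Mcm2 (0.97, 0.0244) and Mcm3 (0.93, 0.0295). Proliferation genes passed as a list at 5.19e-21 (adjusted p = 0.0814 with an estimated correlation). The glycolytic enzymes Ldha (0.85 ± 0.17, 0.00734) and Eno1 (0.70 ± 0.17, 0.0323) were the 2 of 20 glycolysis genes to rise (5 adjusted over the list alone). Glycolysis passed as a list at 0.00146 (adjusted p = 0.141 with an estimated correlation). The mean of the ribosomal list was 9.24 and 8.96 log2 CPM in the run 2 libraries Tet2 KO 1 and 2, 10.2 and 10.1 in the run 3 libraries Tet2 KO 3 and 4, and 9.37 to 9.85 in the Rosa KO libraries. Without the run term the ribosomal (0.223), oxidative phosphorylation (0.223), glycolysis (0.737) and interferon (0.0923) lists did not pass. Among 34 interferon response genes 4 rose (5 adjusted over the list alone), Ifi27l2a (1.41 ± 0.18, 0.000101), Bst2 (1.06 ± 0.23, 0.0223), Oas3 (0.92 ± 0.22, 0.0305) and Oas1a (0.90 ± 0.23, 0.0454). Interferon genes passed as a list at 0.00144 (adjusted p = 0.0742 with an estimated correlation). The 23 histone genes were higher as a list at 0.00351 (median 0.46, adjusted p = 0.426 with an estimated correlation), with 0 rising alone and 1 adjusted over the list alone. They passed as lower with no run term (0.0196). Ifi27l2a overlaps Ifi27, Ccna2 overlaps Exosc9, Atp5d overlaps Cbarp and Rpl35 overlaps Wdr38, and the Oas genes are close paralogs.

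Of 26 stem-like genes 4 rose and 0 fell in Tet2 KO (5 and 0 adjusted over the list alone), namely Tcf7, Slamf6, Il7r and Xcl1. The median was 0.27 and the list was higher (adjusted p = 4.58e-06, adjusted p = 0.0742 with an estimated correlation). Of 27 terminal exhaustion genes 6 fell and 0 rose (8 and 1 adjusted over the list alone), among them Entpd1, Bhlhe40 (−1.20 ± 0.18, 0.00044), Rgs1 (−1.18 ± 0.19, 0.000852) and the orphan receptor gene Nr4a2 (−1.15 ± 0.25, 0.0201). The list was lower, with a median of −0.24 (3.09e-07, adjusted p = 0.0352 with an estimated correlation). Of 33 effector and cytotoxic genes 9 fell and 2 rose (14 and 4 adjusted over the list alone). Itgam (−1.33 ± 0.19, 0.000415) and the death ligand Fasl (−1.27 ± 0.19, 0.000415) fell, and the effector list was lower at 7.95e-09 (median −0.27, adjusted p = 0.0938 with an estimated correlation). The 2 that rose, S100a6 (0.76 ± 0.18, 0.0305) and Anxa2 (0.94 ± 0.17, 0.00411), are calcium-binding proteins and were named after their values were seen. With no run term Anxa2 (0.672) and S100a6 did not pass. Itga1 fell (−1.77 ± 0.28, 0.000761) and Xcl1 rose among 12 tissue residency genes, 2 and 2 adjusted over the list alone. The list did not pass (0.0558), but was lower by fry (0.023) and with genes shared between lists left out (0.0139). Of 12 NK cell markers 3 fell, Klrb1c (−2.38 ± 0.43, 0.00588), Klrb1b (−3.82 ± 0.91, 0.0317) and Il12rb2 (−1.65 ± 0.40, 0.0346). The NK cell list passed at 0.0409 (adjusted p = 0.0972 with an estimated correlation), with 3 falling and 1 rising adjusted over the list alone. That NK cell call was lost without Rosa KO 3 (0.057), Rosa KO 4 (0.085), Rosa KO 5 (0.053), Tet2 KO 2 (0.089) or Tet2 KO 4 (0.10). The B cell list did not pass (0.596), with Tet2 KO 2 at 3.29 log2 CPM and the other Tet2 KO libraries at 7.34 to 7.90. It passed without Rosa KO 1 (0.0108), Tet2 KO 1 (0.0194) or, with the direction turned, Tet2 KO 2 (0.033).

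**Figure D3:**
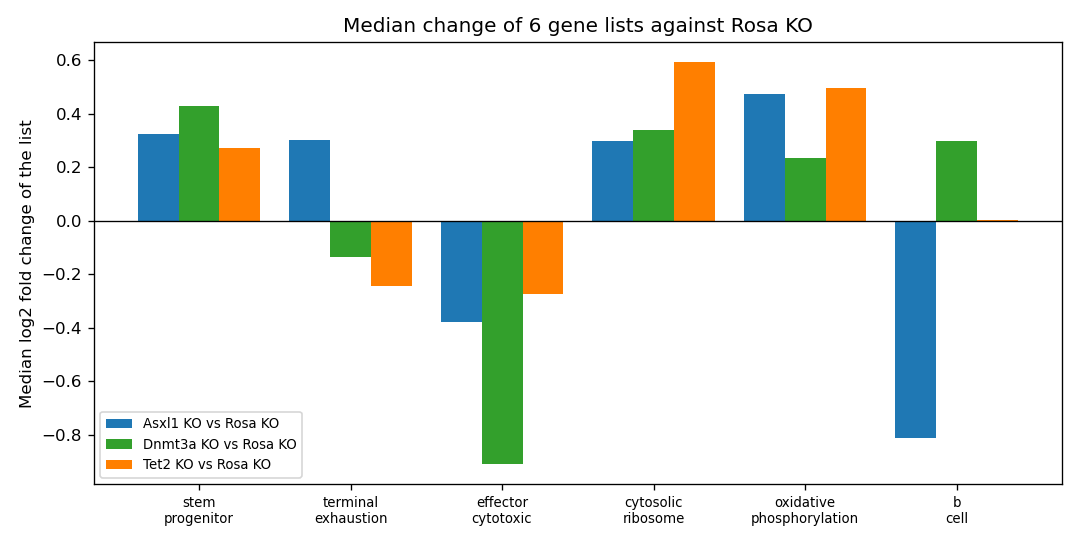
Median log2 fold change against Rosa KO of the members of 6 gene lists in Asxl1 KO, Dnmt3a KO and Tet2 KO, from the model with the run term. The effector and cytotoxic list had medians of −0.38, −0.91 and −0.27 and the stem-like list 0.33, 0.43 and 0.27.

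Lists that did not pass in any of the 3 comparisons with Rosa KO were those of p53 response, Polycomb, DNA methylation machinery, tissue residency, myeloid cells, neutrophils, dendritic cells, erythroid cells and platelets, and sex-linked genes. Their adjusted p-values, in the order Asxl1 KO, Dnmt3a KO and Tet2 KO, were 0.076, 0.680 and 0.596 for p53 response, 0.737, 0.702 and 0.557 for Polycomb, and 0.298, 0.656 and 0.596 for DNA methylation machinery. The values were 0.516, 0.680 and 0.739 for myeloid cells, 0.986, 0.680 and 0.596 for neutrophils, and 0.709, 0.680 and 0.596 for dendritic cells. Erythroid cells and platelets had 0.709, 0.680 and 0.705, and sex-linked genes 0.108, 0.680 and 0.596. Histone genes did not pass in Asxl1 KO (0.902) or Dnmt3a KO (0.313), and glycolysis genes not in Asxl1 KO (0.226). The same held for interferon response genes in Dnmt3a KO (0.394) and immediate early genes in Dnmt3a KO (0.157) or Tet2 KO (0.054). CD4 markers did not pass in Asxl1 KO (0.108) or Tet2 KO (0.744), nor did plasma cell genes in Dnmt3a KO (0.159) or Tet2 KO (0.170). Removal of 1 library gave a call for p53 response in Asxl1 KO without Rosa KO 2 (0.0468) or Asxl1 KO 3 (0.0393), and for histone genes (0.00489) and immediate early genes (0.024) in Dnmt3a KO without Dnmt3a KO 3. In Tet2 KO it gave one for immediate early genes without Rosa KO 1 (0.0185), Rosa KO 5 (0.0426) or Tet2 KO 1 (0.000318), and for plasma cell genes without Tet2 KO 1 (0.0213). The same was seen for myeloid cells without Tet2 KO 2 (0.0107), and for tissue residency without Tet2 KO 1 (0.0351), Tet2 KO 2 (0.0441) or Rosa KO 5 (0.03). Fits with no run term called p53 response (0.0211) and histone genes (0.0134) in Asxl1 KO, erythroid (0.0145) and immediate early genes (7.67e-06) in Dnmt3a KO, and B cell (0.000896), neutrophil (0.000896), plasma cell (0.000233), immediate early (1.34e-05) and residency genes (0.0122) in Tet2 KO. Covariates for other cell types gave calls for immediate early genes in Dnmt3a KO (0.00348) and Tet2 KO (0.0185), dendritic cell genes in Dnmt3a KO (0.0252) and residency genes in Tet2 KO (0.0178). Removal of the length and GC trend gave one for immediate early genes in Tet2 KO (0.025). Without both Asxl1 KO 1 and Tet2 KO 2, myeloid genes passed in Asxl1 KO (0.0304) and Tet2 KO (0.0107) and immediate early and residency genes in Dnmt3a KO (0.03 each), and without both Asxl1 KO 3 and 4, p53 response in Asxl1 KO (0.0162). Among these lists, the median, the mean and the test differed in sign for Polycomb and sex-linked genes in Asxl1 KO and Dnmt3a KO, and for histone, neutrophil and erythroid genes in Asxl1 KO. In Tet2 KO they differed for p53, B cell, neutrophil, erythroid, CD4 and sex-linked genes. Only Hoxb4 of the Hox genes was tested (log2 fold changes 0.86 ± 0.91, 0.46 ± 1.13 and 0.65 ± 0.96), and of the gamma delta T cell genes only Blk (−1.11, 0.73 and −0.12) and Maf (0.68, 0.25 and −0.16), none of which passed.

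The 3 comparisons with Rosa KO shared called genes. Tcf7, Kbtbd11 and Dut were higher and 12 genes were lower in all 3 knockouts. These were Zeb2, S1pr5, Itgam, Klrg1, Klrb1c, Klrc2, Klre1, Il18rap, Itga1, Ccl9, Nabp1 and Bcl2l11, and several of them were named after their values were seen. With no run term S1pr5, Itgam, Klrb1c and Ccl9 of these 15 passed in all 3 knockouts and Klrc2 turned in direction in Tet2 KO (0.13), and with covariates for other cell types Klrb1c and Kbtbd11 passed. Asxl1 KO and Tet2 KO shared 35 genes that rose and 23 that fell, with 2 in opposite directions, where independent lists would share 1.12 and 0.550. Asxl1 KO and Dnmt3a KO shared 3 and 17 (0.041 and 0.205 for independent lists), and Dnmt3a KO and Tet2 KO shared 4 and 16 (0.049 and 0.121). In place of 58, 20 and 20 genes shared in the same direction, the models with no run term gave 6, 8 and 6 and those with covariates for other cell types 19, 2 and 3. Because the comparisons use the same Rosa KO libraries, 20 simulations of unchanged groups were run. Each called at most 1 gene per comparison, so they could share no more than 1 (at most 0, 0 and 1 were shared) and give no scale for longer lists. When each knockout was set against its own part of the split controls, a median of 15 genes were shared by Asxl1 KO and Tet2 KO (11 to 18 over 10 splits), 11 by Asxl1 KO and Dnmt3a KO (8.5 to 13) and 9.75 by Dnmt3a KO and Tet2 KO (8.5 to 11). Across genes, which are not independent replicates, the covariance of log2 fold changes was 0.772 for Asxl1 KO and Tet2 KO against 0.404 in the simulations. It was 0.762 against 0.471 for Asxl1 KO and Dnmt3a KO, and 0.844 against 0.497 for Dnmt3a KO and Tet2 KO. The correlations were 0.60, 0.52 and 0.60 against simulated values of 0.48, 0.49 and 0.50, and had medians of 0.121, 0.136 and 0.155 with split controls.

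The knockouts were also compared with each other. Asxl1 KO had higher levels of exhaustion genes than Tet2 KO, with 9 of 27 members higher and 0 lower (14 and 0 adjusted over the list alone), a median of 0.61 and an adjusted p of 1.51e-27 (adjusted p = 6.97e-05 with an estimated correlation). Entpd1 (1.47 ± 0.16, SE, n = 4 and 4, adjusted p = 8.5e-06), Cd7 (2.01 ± 0.23, 1.27e-05), Tox (1.20 ± 0.15, 2.46e-05), Lag3 (1.56 ± 0.21, 9.89e-05) and Pdcd1 (1.09 ± 0.20, 0.00449) were higher in Asxl1 KO. Gzma was lower (−1.61 ± 0.17, 8.5e-06), and these genes were named after their values were seen. Tox did not pass with no run term (0.105), nor Pdcd1 with covariates for other cell types (0.0576). By the rule, Cd200r2 (5.83), Glp1r (4.12 ± 0.46, 2.9e-05), Prrt1 (3.49), Gpr55 (3.27 ± 0.38, 1.53e-05) and Sept4 (3.26 ± 0.46, 0.0002) were highest. Hspa1b (−5.76, 0.0362), Cdc20b (−4.30, 0.00449), Nebl (−2.27, 0.0362), Slc9a7 (−1.71) and Ifrd1 (−1.52) were lowest. There were 62 genes higher and 16 lower. Without 1 library 35 (without Tet2 KO 3), 40 (Asxl1 KO 4), 47 (Asxl1 KO 3), 48 (Tet2 KO 4) or 49 (Tet2 KO 1) in place of 78 passed. In run 3 alone 53 genes were higher and 106 lower, 42 of these 159 in common with the 78, and in run 2 alone 14 and 10. Of the 10 genes of the rule 4 passed in run 3 and 2 in run 2 (Nebl at −1.21), with their signs kept. Ribosomal genes (median −0.31, 1.38e-12, adjusted p = 0.421 with an estimated correlation) and proliferation genes (−0.26, 0.000119, adjusted p = 0.538 with an estimated correlation) were lower in Asxl1 KO as lists. Histone genes (−0.45, 0.000478, adjusted p = 0.42 with an estimated correlation) and B cell genes (−0.92, 0.000475, adjusted p = 0.57 with an estimated correlation) were lower too. So were immediate early genes (0.004, adjusted p = 0.47 with an estimated correlation) and effector genes (−0.24, 0.0318, adjusted p = 0.574 with an estimated correlation). CD4 markers were higher (0.83, 0.0206, adjusted p = 0.224 with an estimated correlation). Calls were lost without Tet2 KO 1 for B cell (0.737), effector (0.187) and immediate early genes (0.286) and without Asxl1 KO 2 for effector and immediate early genes (0.525 each, the first turned in direction). They were lost without Tet2 KO 2 for effector genes (0.236), without Asxl1 KO 3 (0.162) or Asxl1 KO 4 (0.19) for B cell genes and without Asxl1 KO 4 for CD4 markers (0.0521). With genes shared between lists left out the effector call also ended (0.159). The ribosomal (0.586), histone (0.637), proliferation (0.183) and effector (0.221) calls ended with no run term, and the effector call (0.0516) with covariates for other cell types, as did the CD4 call (0.743), whose list is itself a covariate.

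Exhaustion genes were also higher in Asxl1 KO than in Dnmt3a KO, with 8 of 27 members higher and 0 lower (13 and 3 adjusted over the list alone), a median of 0.48 and adjusted p of 1.38e-10 (adjusted p = 0.0051 with an estimated correlation). The rule named Lcn4 (2.68, adjusted p = 0.0377), Sept4 (2.54 ± 0.46, 0.00982), Gpr55 (2.49 ± 0.38, 0.00303), Glp1r (2.27, 0.0266) and Atp8a2 (2.14, 0.00793) as highest in Asxl1 KO. It named Rapgef4 (−4.11, 0.04996), Ifrd1 (−1.81 ± 0.30, 0.00451), Ttn (−1.74, 0.0287), Slc9a7 (−1.73, 0.0266) and Neurl3 (−1.46, 0.00509) as lowest. There were 38 genes higher and 11 lower (161 and 148 with no filter on low counts). The count of 49 became 11 (without Dnmt3a KO 1), 16 (Dnmt3a KO 2), 19 (Asxl1 KO 1), 20 (Dnmt3a KO 3), 26 (Asxl1 KO 3), 27 (Asxl1 KO 4) or 236 (Asxl1 KO 2). Within run 1 1301 genes passed (1 Asxl1 KO against 2 Dnmt3a KO libraries), with the spread taken from those 2 libraries alone. Within run 2, where Asxl1 KO also had 1 library, no gene passed by edgeR (DESeq2 was not run within a run). Of the 10 genes of the rule 9 passed in run 1. In run 2 they kept their sign, with Lcn4 (1.73), Rapgef4 (−1.54), Ifrd1 (−1.15), Slc9a7 (−1.15) and Neurl3 (−0.87) over 1.5 times smaller. B cell genes (−1.16, 1.38e-10, adjusted p = 0.484 with an estimated correlation), plasma cell genes (0.000267, adjusted p = 0.48 with an estimated correlation) and immediate early genes (0.00476, adjusted p = 0.48 with an estimated correlation) were lower in Asxl1 KO. Effector genes (0.26, 0.00045, adjusted p = 0.484 with an estimated correlation) and oxidative phosphorylation genes (0.25, 0.00126, adjusted p = 0.552 with an estimated correlation) were higher. Calls were lost for oxidative phosphorylation genes without Asxl1 KO 1 (0.173) or Dnmt3a KO 3 (0.0566) and for immediate early genes without Dnmt3a KO 3 (0.0566) or Asxl1 KO 2 (0.638). Immediate early (0.335) and plasma cell (0.199) calls ended with no run term. Covariates for other cell types ended those of effector (0.105), oxidative phosphorylation (0.0819), immediate early and plasma cell genes (0.244 each).

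Dnmt3a KO and Tet2 KO differed in 13 genes, 3 higher and 10 lower in Dnmt3a KO (36 and 30 with no filter on low counts, 89 and 102 by DESeq2). Ubash3b, a negative regulator of T cell receptor signalling, had 220 ± 12.6 CPM in Dnmt3a KO and 62.6 ± 20.8 CPM in Tet2 KO (SD, n = 4 and 4), a log2 fold change of 1.55 ± 0.18 (SE, adjusted p = 6.67e-05). Twsg1 (1.28, 0.0237) and Xdh (1.25, 0.0169) were the other 2 genes higher. Klrb1f (−2.46, 0.0445), Klra9 (−2.12, 0.0169), Ctla2a (−1.30, 0.0237) and Klrk1 (−1.12, 0.0392) were lower by the rule. So was Ccr2 (−1.73 ± 0.18, 1.43e-05), a member of the myeloid list named after its value was seen, whose call ended with no run term (0.232) and with covariates for other cell types (0.0733). Effector genes were lower in Dnmt3a KO as a list, with 3 of 33 members lower (8 adjusted over the list alone) and an adjusted p of 1.05e-11 (median −0.43, adjusted p = 0.174 with an estimated correlation). So were ribosomal (−0.26, 1.05e-11, adjusted p = 0.353 with an estimated correlation) and oxidative phosphorylation (−0.24, 2.22e-07, adjusted p = 0.286 with an estimated correlation) genes. Proliferation (−0.27, 0.0136, adjusted p = 0.81 with an estimated correlation) and interferon response genes (−0.16, 0.014, adjusted p = 0.25 with an estimated correlation) were lower as well. CD4 markers (0.86, 5.01e-05, adjusted p = 0.0286 with an estimated correlation) and exhaustion genes (0.28, 0.00453, adjusted p = 0.242 with an estimated correlation) were higher. B cell genes (0.23, 0.000898, adjusted p = 0.798 with an estimated correlation) and plasma cell genes (0.000761, adjusted p = 0.29 with an estimated correlation) were higher too. The count of 13 became 2 without Dnmt3a KO 3, Tet2 KO 1 or Tet2 KO 2, 5 without Dnmt3a KO 4, and 6 without Dnmt3a KO 2 or Tet2 KO 3, and Ubash3b passed in each of these fits. List calls were lost for B cell genes without Dnmt3a KO 3 (0.118) or, with the direction turned, Tet2 KO 2 (0.0328), and for plasma cell genes without Tet2 KO 2 (0.437). They were lost for proliferation genes without Dnmt3a KO 3 (0.929), Tet2 KO 3 (0.216) or Tet2 KO 4 (0.0699) and for interferon genes without Tet2 KO 3 (0.0745). Calls of B cell and plasma cell (0.445 each), proliferation (0.521) and interferon genes (0.338) ended with no run term. Those of proliferation (0.366) and exhaustion genes (0.211) ended with covariates for other cell types, as did that of CD4 markers (0.527), whose list is itself a covariate. Within run 2, the only run with both groups, 12 genes passed, 7 in common with the 13.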

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

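Of the tests in this part, those of the higher Tcf7 and lower effector genes, the means of the ribosomal and oxidative phosphorylation lists within run 3, the splits within runs, the spread of reads over olfactory and vomeronasal receptor genes and the comparison with the other Asxl1 KO libraries were chosen only after the result was seen, as was the setting that removes a trend with transcript length. In 17 of 116 tests of single libraries within a group 1 library stood far from the others, where chance gives about 1 in 20. Rosa KO 1, the 1 Rosa KO library of run 1, stood apart most often. Its Asxl1 level was 160.8 CPM against 82.09 to 98.21 in the other Rosa KO libraries, Tcf7 was 101.8 against 14.16 to 24.63 CPM, Tox was 1142.2 against 436.8 to 537.5 CPM and Lag3 was 95.57 against 51.75 to 60.1 CPM. Ifng was lower there, at 81.92 against 398.2 to 423.3 CPM. The exhaustion list averaged 7.28 log2 CPM in Rosa KO 1 against 6.959 to 7.008, and the B cell list 5.499 against 7.672 to 7.861.

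In Asxl1 KO 1, also from run 1, Tcf7 was at 382.6 CPM against 67.65 to 99.23 in the other Asxl1 KO libraries, and the stem-like list averaged 6.465 log2 CPM against 5.451 to 5.52. The myeloid list was at 5.619 there against 4.733 to 4.77 and the erythroid and platelet list at 3.494 against 1.438 to 1.733. The dendritic cell list was at 3.501 log2 CPM in Asxl1 KO 2 against 2.576 to 2.714. In Tet2 KO 2 the B cell list was at 3.289 log2 CPM against 7.342 to 7.9, the neutrophil list at −2.183 against 1.887 to 2.587 and only 2 gamma delta T cell genes, Blk and Maf, at 2.582 against 4.783 to 5.111. Asxl1 was at 182.3 CPM there against 96.71 to 109.6 in the others. The B cell list was at 5.756 log2 CPM in Dnmt3a KO 4 against 7.293 to 7.433.

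Some effects against Rosa KO differed between knockouts by a direct test. Itgb1, an integrin subunit named after its values were seen, was at −0.63 in Asxl1 KO and 0.69 in Tet2 KO, a difference of −1.323 on the log2 scale (adjusted p = 1.4e-05). With no run term neither effect passed against Rosa KO (0.315 and 0.172), while the difference did (0.00359). Tox was at 0.56 and −0.65, a difference of 1.202 (2.46e-05), which did not pass with no run term (0.105). Members of the exhaustion list had a median log2 fold change of 0.485 in Asxl1 KO against Dnmt3a KO (1.38e-10) and 0.6056 against Tet2 KO (1.51e-27), and members of the B cell list one of −1.157 in Asxl1 KO against Dnmt3a KO (1.38e-10). With an estimated correlation the exhaustion calls held (adjusted p = 0.0051 and 6.97e-05), while the B cell call ended (adjusted p = 0.484 with an estimated correlation), as it did by fry (0.265).

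In Asxl1, Dnmt3a and Tet2 KO Tcf7 was higher (adjusted p = 0.188, 0.183 and 0.723 with no run term) and the effector list lower (adjusted p = 0.0662, 0.00695 and 0.0938 with an estimated correlation), while the mean of 12 pan T cell genes was 0.58 ± 0.16 higher in Asxl1 KO, where that of the effector list was at −0.57 ± 0.12. Dilution by other cells would lower pan T cell genes alike, and a higher T cell share raise effector genes alike. Yet the effector mean lay over 2 SE below the pan T cell mean, which argues against either alone. The differences were −1.156 ± 0.0953 in Asxl1 KO, −1.047 ± 0.113 in Dnmt3a KO and −0.6494 ± 0.1005 in Tet2 KO. The 4 NK cell genes Ncr1, Klra8, Klra1 and Klrb1a summed to 7.783 ± 2.23 CPM in Rosa KO. In the knockouts their sums were 2.899, 8.943 and 6.317 CPM, against falls of Klre1 of 152.7, 157.6 and 102.8 CPM. That argues against loss of cells with these 4 genes as the whole cause of the fall of Klre1. Their lower sum in Asxl1 KO leaves a smaller part open there. The NK cell list, which also holds Klrb1c and Gzma, was lower in all 3 knockouts at the preset correlation. A part from NK cells therefore stays open in each. RNA of B, myeloid or CD4 T cells as the source of Tcf7 was argued against in Tet2 KO, where with their list means as covariates the log2 fold change was 1.858 ± 0.251 (1.95 ± 0.27 before, adjusted p = 0.000276), but stayed open in Asxl1 KO (1.447 ± 0.336, from 1.94 ± 0.26, 0.0996) and Dnmt3a KO (1.426 ± 0.436, from 1.79 ± 0.31, 0.44), where the call ended with a smaller fold and a larger SE. A difference between runs was argued against in Asxl1 KO and Tet2 KO, with Tcf7 at 2.087 ± 0.271 (8.7e-05) and 2.243 ± 0.272 (0.000103) within run 3, and stayed open in Dnmt3a KO, with 0.934 ± 0.235 within run 1 (0.226) against 1 Rosa KO library. An effect of the knockout on T cell state was not tested by itself and stays open in all 3 knockouts.

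Ribosomal and oxidative phosphorylation genes, whose median transcript lengths were 645 and 617.5 bases against 1418 for the tested genes, were higher as lists in Asxl1 KO (adjusted p = 0.340 and 0.175 with an estimated correlation) and Tet2 KO (adjusted p = 0.0742 for each with an estimated correlation). With a trend in transcript length and GC content removed, the ribosomal mean was 0.2437 ± 0.114 in Asxl1 KO (0.322 ± 0.133 before) and 0.5182 ± 0.12 in Tet2 KO (0.623 ± 0.141 before), and the oxidative phosphorylation mean 0.4882 ± 0.109 (0.521 ± 0.126) and 0.4949 ± 0.115 (0.57 ± 0.133). Each stayed over 2 SE above 0, with the list called at the preset correlation. That argues against the trend as the whole cause, except for ribosomal genes in Asxl1 KO, barely over 2 SE. Within run 3 (2 libraries per knockout, 4 of Rosa KO) the ribosomal mean rose by 0.47 ± 0.16 in Asxl1 KO and 0.60 ± 0.16 in Tet2 KO. The other mean rose by 0.48 ± 0.15 and 0.53 ± 0.15. Over 2 SE each, these argue against a run difference as the whole cause. In Asxl1 KO they rest on libraries 3 and 4, flagged below, without which the ribosomal list did not pass. Nor did it with no run term in Asxl1 KO (0.761) or Tet2 KO (0.223), nor the oxidative phosphorylation list in Tet2 KO (0.223). An untested effect of the knockout stays open.

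Asxl1 KO 3 and 4 had the most genes with at least 1 count. Thinned to the same total they still had 15452 and 16533, against at most 14631 elsewhere, which argues against depth. Asxl1 KO 1 had the fewest, 12375, but Asxl1 KO 2 had 14247, over the other groups' median of 13607. A knockout effect stays open. Olfactory and vomeronasal receptor genes, not known to be used by T cells, held 197.2 and 334.5 CPM in the 2 libraries against up to 237.2 elsewhere, a measure that a few genes dominate and that leaves the question open. At equal depth, however, 172 and 318 of 1446 such genes had a read there, against 17 to 70 in the other libraries. Background reads spread over many genes are a candidate source in these 2 libraries, and without both of them 93 genes passed in Asxl1 KO against Rosa KO, 51 of them in common with the 227.

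Other splits of the same libraries into groups of the same sizes were fitted to see whether chance could give as many genes. For Asxl1 KO against Rosa KO 1 of 100 splits, the real one, gave 227 genes, and the highest other gave 156. It set Rosa KO 2 to 5, all of run 3, against the rest, and so differed from the real split by Rosa KO 1 alone. For Dnmt3a KO 1 of 100 gave 30 (highest other 14, again Rosa KO 2 to 5 against the rest, which parts run 3 from runs 1 and 2), and for Tet2 KO 1 of 100 gave 204 (highest other 2). For Asxl1 KO against Dnmt3a KO 1 of 35 gave 49 (highest other 15), and against Tet2 KO 1 of 35 gave 78 (highest other 45). For these 5 the share of splits with as many genes lay under 0.05. Run alone took a median of 25.6% of a gene's variance (12.5% by its degrees of freedom), so libraries of different runs are not interchangeable. Splits across runs therefore cannot exclude chance. For Dnmt3a KO against Tet2 KO 2 of 35 splits gave at least 13, and the other one, with 16 genes, parted run 2 from runs 1 and 3, so chance is not excluded, and within run 2 alone 12 genes passed. With libraries exchanged only within a run, 1 of 30 splits, the real one, gave 227 genes for Asxl1 KO against Rosa KO (highest other 25). That share lies under 0.05 for this comparison taken alone, with no correction for the 6 comparisons. The other comparisons have too few such splits for a share under 0.05. The real split gave 30 genes for Dnmt3a KO (3 splits, highest other 0) and 204 for Tet2 KO (15 splits, 0) against Rosa KO. Between knockouts it gave 49 for Asxl1 and Dnmt3a KO (9 splits, 15), 78 for Asxl1 and Tet2 KO (18 splits, 45) and 13 for Dnmt3a and Tet2 KO (6 splits, 0).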

How the results depend on the processing

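The settings without Asxl1 KO 1 and Tet2 KO 2, without Asxl1 KO 3 and 4, with covariates for other cell types and with a transcript length and GC trend removed were chosen only after the data were seen. Counts are given in the order Asxl1, Dnmt3a and Tet2 KO against Rosa KO, then Asxl1 against Dnmt3a KO, Asxl1 against Tet2 KO and Dnmt3a against Tet2 KO (227, 30, 204, 49, 78 and 13 genes with all libraries). Of 142 called values of named genes, DESeq2 kept 142, RLE size factors 137 and no filter 141. The length trend kept 115, the covariates 66 and no run term 52. No sign changed, which with no run term the rule asked of its largest changes. Of all 204 Tet2 KO calls 200 kept it there. Fits without 1 library kept 875 of 1250 calls and every sign. The cause of the changes below was not tested, except that settings with fewer libraries test fewer samples. In run 1 alone (1 library each) Klf6 turned in sign in Asxl1 KO (0.0075). Rosa KO 5 had the fewest counts, with 13730 genes detected, and the effect of depth on low genes was not measured per library.

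With no filter 568, about 1.2e+02 (49 higher and 76 lower), 378, 309, 192 and 66 genes passed, and by DESeq2 920, 309, 641, 473, 361 and 191. Without the run term the counts were 23, 19, 23, 6, 27 and 1, and the overlaps between knockouts were 8 (Asxl1 and Dnmt3a), 6 (Asxl1 and Tet2) and 6 genes in place of 20, 58 and 20. With split controls and the run term their medians were 11, 15 and 9.75, and with the covariates they were 2, 19 and 3. With only the libraries of the 2 groups 19 genes passed between Asxl1 and Dnmt3a KO. Within run 1 607 genes passed for Asxl1 KO and 1301 between Asxl1 and Dnmt3a KO, with 1 residual degree of freedom from the 2 Dnmt3a KO libraries, like which the lone libraries were assumed to vary. Within run 2 edgeR called 0 between Asxl1 and Dnmt3a KO (509 at an unadjusted p under 0.05) and 24 between Asxl1 and Tet2 KO. Within run 3 614 passed for Asxl1 KO, 403 for Tet2 KO and 159 between them. Without Asxl1 KO 1 and Tet2 KO 2 there were 423 for Tet2 KO and 27 between Asxl1 and Dnmt3a KO. Without Asxl1 KO 3 and 4 there were 93, 30 and 44 in the 3 comparisons of Asxl1 KO. With the covariates there were 27, 3, 14, 21 and 1, leaving out Tet2 KO against Rosa KO, where 186 passed. Leaving out 1 library gave 80 to 373, 21 to 36, 33 to 199, 11 to 236, 35 to 87 and 2 to 11 genes.

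The replicate number as a block gave 12, 19, 26, 2, 17 and 2 genes with no run term, and 51, 0, 52, 2, 37 and 1 with it. With both terms edgeR called 0 for Dnmt3a KO (DESeq2 was run without the block only). There 850 of 13881 genes had an unadjusted p under 0.05, where chance alone would give about 694. Within a run the median correlation of deviations was 0.078 for equal numbers and 0.045 otherwise. Of 17 libraries 4 correlated best with their own number and 14 with their own run. Pairing within a run stays open. With the block and no run term, Dnmt3a was at 0.52 in Dnmt3a KO and Tet2 at 0.19 in Tet2 KO, 5 lists passed between Asxl1 and Tet2 KO, and these lists turned in direction: ribosome in Asxl1 KO (adjusted p = 0.651), B cell (0.19), ribosome (3.56e-05), histone (0.00121), oxidative phosphorylation (0.00211) and plasma cell (0.0366) in Dnmt3a KO, glycolysis (0.886), histone (0.0174) and myeloid (0.00198) in Tet2 KO, and ribosome between Asxl1 and Dnmt3a KO (0.000447).

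For the targeted genes, with no run term the log2 fold changes were 0.017 for Asxl1, 0.44 for Dnmt3a and 0.17 for Tet2. Asxl1 was at 0.18 within run 3 and 0.10 without Asxl1 KO 1 and Tet2 KO 2. Without 1 library the range was −0.30 (without Asxl1 KO 4) to 0.14 (without Rosa KO 1) for Asxl1 and −0.19 (without Rosa KO 3) to 0.22 (without Rosa KO 1) for Dnmt3a.

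Of the lists, 11, 10, 10, 6, 8 and 9 passed in the 6 comparisons. With an estimated correlation 0, 3, 1, 1, 1 and 1 passed, and by fry 5, 3, 1, 1 and 1, leaving out Tet2 KO against Rosa KO. With genes shared between lists left out, the stem-like (0.117) and interferon (0.0634) calls in Asxl1 KO and the effector call between Asxl1 and Tet2 KO (0.159) ended, and residency genes passed in Dnmt3a KO (0.0338) and Tet2 KO (0.0139). Between Asxl1 and Tet2 KO 5 passed with no run term and 13 without Asxl1 KO 1 and Tet2 KO 2. With the covariates 2 passed between Asxl1 and Dnmt3a KO and 5 between Dnmt3a and Tet2 KO. Leaving out 1 library gave 6 (without Rosa KO 1) to 11 for Dnmt3a KO and 5 (without Tet2 KO 1) to 12 (without Asxl1 KO 1) between Asxl1 and Tet2 KO. Without the run term these lists turned in direction: B cell (adjusted p = 0.0613), ribosome (9.13e-05), histone (0.000351), oxidative phosphorylation (0.0133) and plasma cell (0.0182) in Dnmt3a KO, histone (0.0196) and myeloid (0.00926) in Tet2 KO, and ribosome between Asxl1 and Dnmt3a KO (4.73e-05). Without Asxl1 KO 1 and Tet2 KO 2, between Dnmt3a and Tet2 KO, B cell (0.447), myeloid (5.3e-06) and neutrophil (0.0176) turned. Without Asxl1 KO 3 and 4, B cell (0.0014) and plasma cell (0.788) against Rosa KO and B cell (0.00441) and proliferation (0.508) against Tet2 KO turned. With the covariates, one of which is the B cell list itself, B cell turned in Dnmt3a KO (0.849) and in the 3 comparisons between knockouts (0.845, 0.914 and 0.99). Leaving out 1 library turned B cell in Dnmt3a KO (5.32e-05 to 0.289, turned without Rosa KO 1), Tet2 KO (0.0108 to 0.876, without Tet2 KO 2) and Dnmt3a against Tet2 KO (4.77e-10 to 0.118, without Tet2 KO 2), myeloid (5.26e-06 to 0.922) and neutrophil (0.00387 to 0.799) in that last comparison without Tet2 KO 2, and effector genes between Asxl1 and Tet2 KO (0.000107 to 0.525, without Asxl1 KO 2).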

Other observations

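The test of neighbouring genes was fixed before its result was seen, while the genes of the next paragraph were chosen after their values were seen.

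Klre1 and Klrc2, receptor genes of the NK gene complex that T cells with effector functions also use, fell in all 3 knockouts. Klre1 was at −1.60 ± 0.21 in Asxl1 KO (adjusted p = 9.49e-05), −1.50 in Dnmt3a KO (0.00391) and −0.97 in Tet2 KO (0.0344). Klrc2 was at −1.89 ± 0.26 (0.000166), −1.97 ± 0.30 (0.00152) and −1.33 (0.0156). Klrc1, an inhibitory receptor gene, fell in Asxl1 KO (−1.14, 0.0117) and Dnmt3a KO (−1.57, 0.00881) and was at −0.74 (0.192) in Tet2 KO. Klrk1 fell in Dnmt3a KO (−1.18, 0.0273) and did not pass in Asxl1 KO (−0.75, 0.0562) or Tet2 KO (−0.06, 0.949), and Klrb1f, of the same complex, rose in Tet2 KO (2.00, 0.0214). With no run term Klrc2 passed in none of the 3 (−1.28 in Asxl1 KO, 0.563, and −0.87 in Dnmt3a KO, 0.774) and turned in direction in Tet2 KO (0.13, adjusted p = 1), as did Klrk1 there (0.35). Klre1 in Tet2 KO (0.422), Klrc1 in Asxl1 KO (0.114) and Klrk1 in Dnmt3a KO (0.337) did not pass with no run term either. These genes have close paralogs, so their reads may have been shared. Between knockouts, the exhaustion genes Rgs1 (1.17, 0.00451), Id2 (0.89, 0.0187), Cd160 (1.35, 0.0266), Prdm1 (0.87, 0.0464) and Cxcr6 (0.93, 0.0464) were higher in Asxl1 KO than in Dnmt3a KO. With covariates for other cell types only Rgs1 of these passed (0.015), and with no run term only Cd160 (0.0408). The apoptosis gene Bcl2l11 was lower in all 3 knockouts, at −0.84, −1.04 and −0.85, and passed in none of them with no run term (0.379, 0.547 and 0.701). Covariates for other cell types ended the Dnmt3a KO calls of Klrc2 (0.342), Klre1 (0.451), Klrc1 (0.44), Klrk1 (0.451) and Bcl2l11 (0.342) and the Asxl1 KO calls of Klrc1 (0.214) and Bcl2l11 (0.0996).

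A hypothesis was that called genes lie side by side on the chromosomes. In Asxl1 KO 7 adjacent pairs that do not overlap changed the same way, against a median of 1 in 10000 random draws of as many genes, of which 14 had at least 7 and the highest 9. The pairs were Il18r1 and Il18rap, Btg1 and Atp2b1, Gpx8 and Gzma, Klrc2 and Klrc1, Klra13-ps and Klra3, Cd3g and Cd3d, and Slc6a20b and Lztfl1. Several are pairs of related genes that may share regulation or reads, and Gpx8 and Gzma both lie within Cdc20b, so the count is no test of a chromatin effect. In Tet2 KO 1 pair was seen, Klrb1c and Klrb1b, and 7716 of 10000 draws had as many.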
